A study of Astyanax mexicanus with 6 samples.

How the data were processed

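Open chromatin was profiled in liver by ATAC-seq, in which the Tn5 transposase cuts accessible DNA and inserts sequencing adapters, so that stretches dense in fragments mark open chromatin. The species was Astyanax mexicanus, the Mexican tetra, a fish with a river-dwelling surface form and blind cave forms. Per the labels' protocols, livers were Dounce-homogenised in a detergent buffer, about 70000 nuclei entered each reaction, tagmentation lasted 22 to 24 min, and libraries were sequenced with paired ends. The labels give 6 samples in 3 groups (Surface, Pachon cave and Tinaja cave), with replicates numbered 1 and 2 in each, and each sample's label names the same 2 flow cells, so the sequencing run was not confounded with the form.

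The values analysed were 3 peak lists, 1 per form, each recorded under replicate 1 of its form. The submitters' processing notes name bcl2fastq 2.20, Bowtie2, SAMtools and MACS2. Settings, read filters, any shift for the Tn5 insertion offset, duplicate handling and the significance threshold of the peak calling are not given in the sources used here. Nor is it stated there whether a list came from 1 replicate, from pooled reads or from peaks common to both replicates. Each deposited list held 6 columns with the sequence name, start and end of a peak. The deposited score column was 0 for every peak, and name and strand were dots, so no summit, enrichment or q-value ranked the peaks. The lists carry no read counts, so the depth behind each peak is unknown here. A deeper or cleaner library yields more and wider peaks from the same chromatin, so both the number and the width of peaks depend on depth and on the caller as well as on accessibility.

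The labels name no genome build. Unplaced scaffold names carry the prefix APWO02, which, as background, belongs to the second public assembly of the species, built from surface fish. The gene table at hand was for AstMex3 and was not used for positions: on 4 of 25 chromosomes peaks lay beyond the last AstMex3 gene, and on chromosome 3 the largest peak end was 74118900 against a last gene end of 65427310. Coordinates are therefore those of the lists, written 1-based, and no gene, exon or promoter is assigned. The planned gene lists, positions relative to genes and motif matches were not run, since no genome or annotation of the files' build was used. Scaffold names are not printed, and regions on them are given by length.

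Peaks of the 3 lists that overlapped or touched were merged into union regions, and each region was classed by the lists with a peak in it. Pairwise sharing was the percentage of the peaks of both lists that overlapped a peak of the other list by at least 1 bp. Chance sharing came from 100 random placements of each list's peaks on the same sequences, whose ends were taken as the largest peak end. For sharing and for ratios of region counts, 95% intervals came from 1000 resamplings of 1 Mb blocks of the genome (200 for peak widths). They cover variation along the genome, not between fish or libraries. Wilson 95% intervals of shares cover counting error only. With 1 list per form there is no spread between replicates, and no test between forms was made. The planned measures of cave-cave against cave-surface sharing were the shares of regions held by exactly 2 lists and the difference of base-pair Jaccard indices. The excess in percentage points, the partners of Tinaja and the ratio of Surface-only to Pachon-only regions were added after the data were seen. Width comparisons used regions with exactly 1 peak of each list.

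Windows of 1 Mb with at least 20 regions were tested for an excess of a pattern held by 1 or 2 lists. The binomial upper-tail probability of each window's count was set against the 95th percentile of the most extreme value over all windows and 6 patterns in 1000 permutations of the patterns among regions. The longest run of consecutive regions missing from, or held only by, a form was set against 200 permutations in a one-sided test, with Benjamini-Hochberg adjustment over 12 runs. Neighbouring regions need not be independent, which makes both permutation tests too liberal, and they describe these lists, not the forms.

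By the rule fixed before the data were examined, the regions named are the 10 strongest of both caves only, the 10 strongest of Surface only and the 5 strongest of each cave alone. Without scores, strength was the length covered by peaks, the lower of both lists for a region of a pair. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated data made by trimming the ends of the 110214 regions, all (100%) were given their true class. That result was fixed by construction, since trimmed copies of 1 region always overlap and never reach another. It does not cover peaks that are split or overlap only in part. The interval for an excess of cave-cave sharing lay above 0 in 0 of 40 simulations with equal sharing. It lay above 0 in 40 of 40 with regions of both caves made more frequent than those of the other pairs. The simulations with equal sharing drew lists of about equal length. They therefore do not show how often unequal list lengths alone would give an excess. The excess is taken over the larger of 2 cave-surface values, so with equal sharing it tends to lie below 0. Patterns were also drawn independently for each region, without clustering along the genome. The 0 of 40 is therefore not a rate of false calls for the real lists. The window test, run over 1409 windows, found 10 of 10 planted windows with 0 others. The planted windows held many regions, and about 50% of their regions of other classes were made Tinaja-only. Weaker excesses, windows with few regions and excesses of other classes were not planted, so detection of those is not shown. Alternatives were a reciprocal overlap of 50%, an overlap of 25% of the shorter peak, the widest 50% of each list, equal list lengths, 500 bp around each midpoint, chromosomes only, merging of peaks within 200 bp, peaks of 150 to 2000 bp, and windows of 250 kb and 5 Mb.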

Results

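Liver open chromatin was compared between the surface form of Astyanax mexicanus and fish of 2 cave forms, Pachon and Tinaja. Each form had 2 samples by the labels and 1 peak list. The Surface list held 73380 peaks covering 51.9 Mb, the Pachon list 72521 peaks covering 48.1 Mb and the Tinaja list 84653 peaks covering 56.9 Mb. Median peak width was 540 bp in Surface, 502 bp in Pachon and 506 bp in Tinaja. The share of peaks on the 25 assembled chromosomes was 69.4% in Surface, 69.1% in Pachon and 68.8% in Tinaja, and the remainder lay on unplaced scaffolds. With no replicate lists, differences between forms below are differences between these 3 lists.

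Pachon and Surface differed little in number of peaks, whereas the Tinaja list was longer. Pachon had 859 peaks fewer than Surface (1.17%), and Tinaja had 11273 more (15.4%). The surplus of Tinaja lay in peaks under 1000 bp. Tinaja had 41646 peaks under 500 bp against 33580 in Surface, a ratio of 1.24, and 30255 peaks of at least 500 and under 1000 bp against 26828, a ratio of 1.13, but 12752 peaks of at least 1000 bp against 12972 in Surface, a ratio of 0.983 (block-resampled 95% interval 0.966 to 1.00). Pachon had 10413 peaks of at least 1000 bp, 0.803 of the Surface number.

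Regions open in all 3 forms were the most numerous class and the widest, and those held by a single list were narrow. The 3 lists merged into 110214 regions. Of these, 46041 (41.8%, Wilson 95% interval 41.5 to 42.1) were open in all 3 forms, 23347 (21.2%) in exactly 2 and 40826 (37.0%) in 1 only. The median length was 804 bp for regions of all 3 forms, 532 bp for those of both caves only, 354 bp for Surface only, 326 bp for Pachon only and 342 bp for Tinaja only. These are lengths of merged peaks, so regions held by more lists are longer in part by construction. Where all 3 lists held exactly 1 peak, the peaks themselves had median widths of 649 bp in Surface, 595 bp in Pachon and 635 bp in Tinaja. Single-list regions made up 19.9% of the regions held by Surface, 12.0% of those held by Pachon and 21.7% of those held by Tinaja. Under a reciprocal overlap of 50%, Surface-only regions rose in number from 14326 to 22261 and Pachon-only regions from 8489 to 15069.

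**Figure D1:**
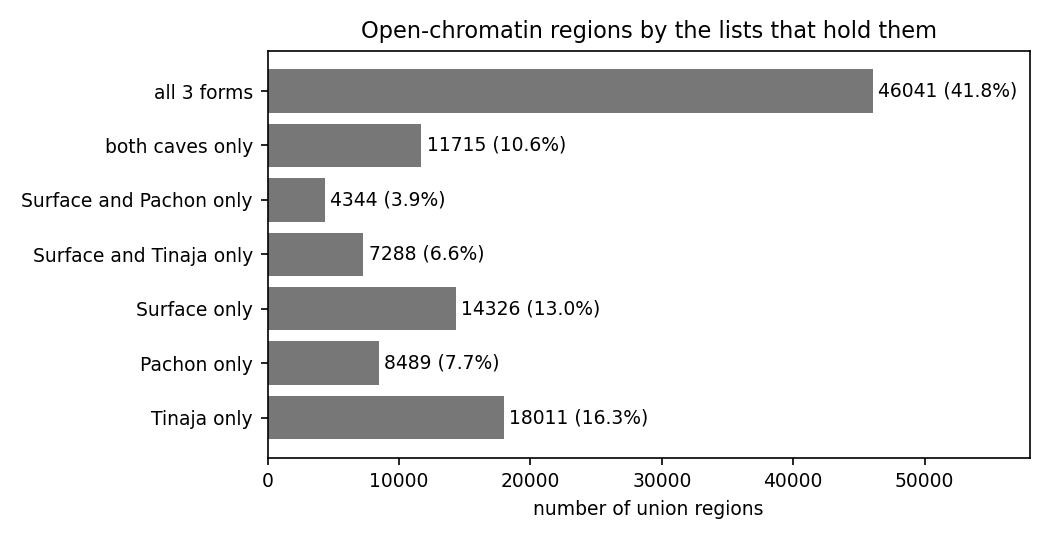
Number of union regions (x axis, counts) for each combination of lists that hold a peak there, with the percentage of all 110214 regions beside each bar. Regions of all 3 forms were the most numerous class with 46041, and among pairs the class of both caves only was the largest in these full lists, with 11715.

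All pairs of lists overlapped far more than randomly placed peaks. Of the peaks in the Pachon and Tinaja lists together, 75.3% overlapped a peak of the other list (block-resampled 95% interval 74.9 to 75.7), against 8.55% for random placement. For Surface and Pachon the value was 70.7% (interval 70.3 to 71.1), against 8.19% at random, and for Surface and Tinaja 69.0% (interval 68.6 to 69.5), against 8.76% at random. Counted in base pairs, the Jaccard index, the overlap divided by the union, was 0.571 for the caves, 0.504 for Surface and Pachon and 0.489 for Surface and Tinaja.

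Sharing grew with peak width in every pair. Of Surface peaks under 300 bp, 42.9% overlapped a Pachon peak and 51.4% a Tinaja peak, and of Surface peaks of at least 1000 bp the shares were 91.4% and 91.8%. Of Tinaja peaks under 300 bp, 37.8% overlapped Pachon and 36.7% Surface, with Wilson 95% intervals of 37.0 to 38.6 and 35.9 to 37.5. Both shares are of the same peaks, so comparing these intervals does not test their difference. For Tinaja peaks of at least 1000 bp the shares were 91.0% (interval 90.5 to 91.5) in Pachon and 84.9% (interval 84.3 to 85.5) in Surface.

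**Figure D2:**
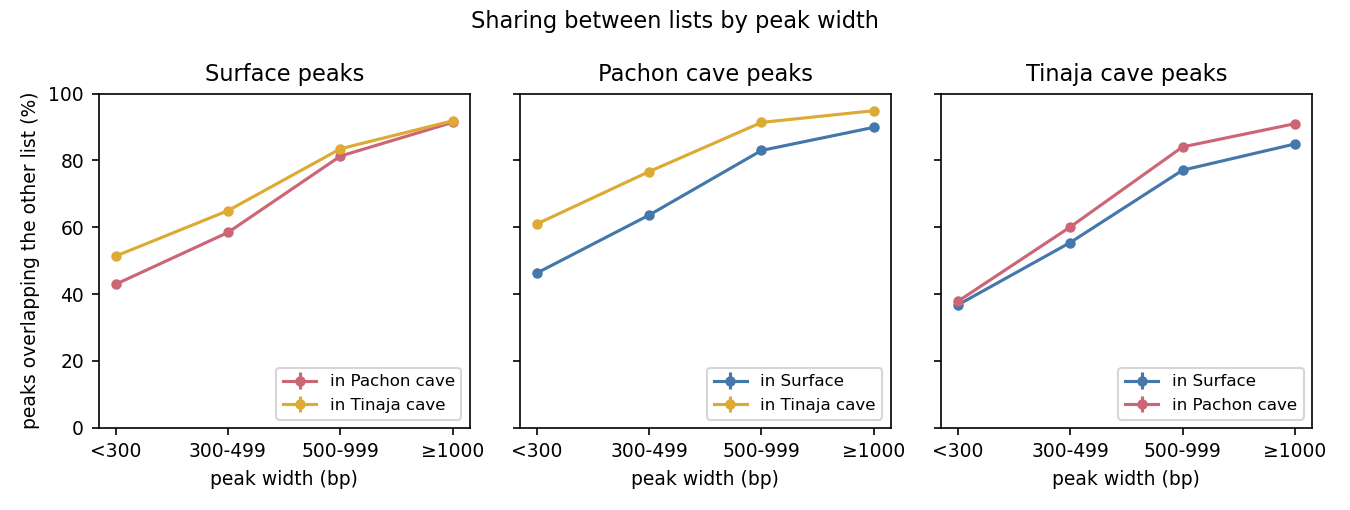
Percentage of the peaks of each list (panels) that overlap a peak of another list (colours), by peak width in bp; error bars are Wilson 95% intervals and are smaller than most points. Sharing rises with width in every panel, and Pachon peaks lie higher with Tinaja than with Surface in each width class, from 60.9% against 46.3% under 300 bp to 94.9% against 89.9% at 1000 bp or more.

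The design sets 2 cave forms against 1 surface form and so asks whether the cave livers share open chromatin with each other beyond what each shares with the surface liver. In these lists they did. Regions open in both caves and not in Surface numbered 11715, or 50.2% of the regions held by exactly 2 lists (block-resampled 95% interval 49.3 to 51.1). Surface and Tinaja alone held 7288 (31.2%, interval 30.4 to 32.0), and Surface and Pachon alone held 4344 (18.6%, interval 18.1 to 19.2). Regions of both caves were thus 1.61 times as numerous as those of Surface and Tinaja (interval 1.55 to 1.67) and 2.70 times as numerous as those of Surface and Pachon (interval 2.58 to 2.82). The Tinaja list can be compared with 2 partners of nearly equal length: 69.6% of its peaks overlapped a Pachon peak and 64.5% a Surface peak, a difference of 5.10 percentage points (interval 4.67 to 5.56). Of Pachon peaks, 81.9% overlapped Tinaja and 71.4% Surface, a comparison that the longer Tinaja list favours.

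The Jaccard index of the caves exceeded the larger of the cave-surface indices by 0.0667 (interval 0.0635 to 0.0702), the planned measure. The percentage of peaks shared exceeded the larger cave-surface value by 4.57 points (interval 4.27 to 4.87), a measure that, like the comparison of Tinaja's partners, was added after the data were seen. When each list was thinned at random to the shortest length, which removes peaks almost only from Tinaja, the difference of Jaccard indices was 0.00952 (interval 0.00589 to 0.0134), that in points became -0.391 (interval -0.738 to -0.0655), and the comparison of Tinaja's partners was 5.81. Regions of both caves were then 0.983 times as numerous as those of Surface and Pachon (interval 0.947 to 1.019), with 10691 regions of Surface and Pachon against 10513. Keeping the same number of widest peaks instead gave an excess of 4.93 (interval 4.61 to 5.24) and a ratio of 1.53 (interval 1.47 to 1.59). That setting drops almost only Tinaja's narrowest peaks, which are its least shared, and so favours its pairs.

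In the full lists, the preponderance of regions of both caves was spread over the genome. Among regions held by exactly 2 lists, those of both caves were the most frequent on 24 of 25 chromosomes. The exception was chromosome 11, where 79 regions were held by both caves only and 79 by Surface and Tinaja only. The share of both caves ranged from 41.9% on chromosome 2 to 55.9% on chromosome 23. After random thinning to equal length the number of such chromosomes was 7, and with equal numbers of widest peaks it was 25.

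**Figure D3:**
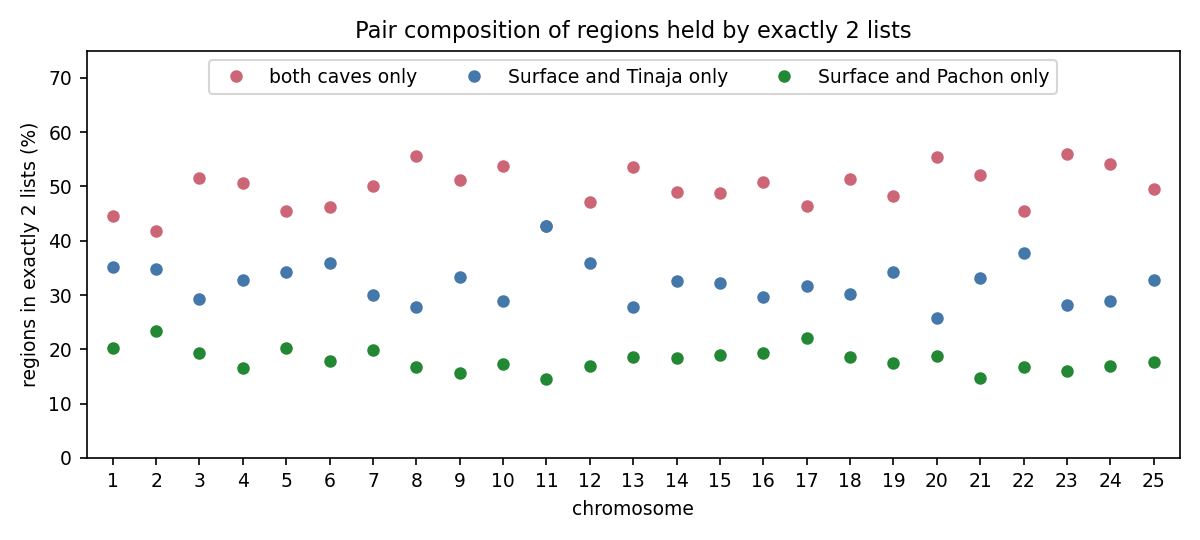
Percentage of the regions held by exactly 2 lists that belong to each pair (colours), for each of the 25 chromosomes (x axis). The points of both caves lie highest on 24 chromosomes, between 41.9% and 55.9% over all 25, and on chromosome 11 the points of both caves and of Surface and Tinaja coincide at 42.7%.

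The 10 strongest regions open in both caves and absent from the Surface list covered 3313 to 5628 bp in the cave list with the lower coverage, and 7 of them lay on unplaced scaffolds. On chromosome 2, positions 18048507 to 18054158, a peak of 5608 bp in Pachon matched a peak of 5652 bp in Tinaja. On chromosome 10, positions 32594068 to 32599325, peaks covered 4445 bp in Pachon and 5258 bp in Tinaja. On chromosome 7, positions 26849025 to 26852564, the peak was 3385 bp wide in Pachon and 3422 bp in Tinaja. The next on chromosomes, listed because scaffold regions carry no position here and so chosen after the values were seen, were at positions 17657359 to 17661518 of chromosome 3 and 24984135 to 24987330 of chromosome 18. All these are far above the median length of 532 bp for the class. Which genes lie there was not analysed here.

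The 10 strongest Surface-only regions were 4158 to 16960 bp long, and 9 lay on unplaced scaffolds. Of these, 3 measured 16960, 11023 and 9609 bp. The remaining region, on chromosome 20 at positions 36235231 to 36239388, was 4158 bp long. Among the 5 strongest of Pachon only, 4 lay on scaffolds, the longest with 4772 bp, and the other was a 3084 bp region of chromosome 6 at positions 1417674 to 1420757. Among the 5 strongest of Tinaja only, 4 lay on scaffolds, the longest with 5214 bp, and the other was a 4501 bp region of chromosome 16 at positions 13367721 to 13372221. Of all 30 regions, 25 kept their class under a reciprocal overlap of 50%, 29 with peaks within 200 bp merged and 24 with 500 bp peaks.

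Where all 3 forms were open, peak widths were close. In 42926 regions with exactly 1 peak of each list, the median width was 649 bp in Surface, 595 bp in Pachon and 635 bp in Tinaja. The median log2 ratio of widths was -0.06 for Pachon over Surface (block-resampled 95% interval -0.06 to -0.05), a ratio of 0.963, and 0.04 for Tinaja over Pachon (interval 0.04 to 0.04), a ratio of 1.03. For Tinaja over Surface the ratio was 0.998 and the interval of its log2 value reached 0, whereas on chromosomes alone the median log2 ratio was -0.0081 (interval -0.012 to -0.0045). Widths differed by a factor of 2 or more in 9.37% of regions between Pachon and Surface, in 9.27% between Tinaja and Surface and in 5.32% between the caves.

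Regions of a single form were not spread evenly. Of 1409 windows of 1 Mb, 24 had an excess of 1 pattern above the threshold set by the permutations. Of these, 21 were rich in Tinaja-only regions, 2 in Surface-only regions and 1 in regions of both caves only. None passed for Pachon-only regions or for the pairs of Surface with 1 cave. All 6 patterns shared 1 threshold, so the same fold excess passes less easily for a rarer pattern. Tinaja-only regions were the most frequent of the 6, with 16.3% of all regions. Pachon-only regions made up 7.70%, those of Surface and Tinaja only 6.61% and those of Surface and Pachon only 3.94%. The window counts therefore do not show that clustering was particular to Tinaja. The lowest permutation p was in a window of chromosome 18 from 33000001 to 34000000, where 35 of 64 regions were Tinaja-only against 10.5 expected (permutation p = 0.001, the smallest that 1000 permutations can give). Windows on chromosome 24 from 11000001 to 12000000 (27 of 55 regions), chromosome 23 from 17000001 to 18000000 (33 of 69) and chromosome 6 from 23000001 to 24000000 (32 of 69) followed, each with permutation p = 0.002. The window for both caves lay on chromosome 3 from 73000001 to 74000000, with 24 of 88 regions against 9.35 expected (permutation p = 0.047). A second test permuted patterns only among regions of similar width and scored each window by its excess over expectation in standard deviations. It passed 11 windows, of which 7 were among the 21 Tinaja-only windows. The others were 2 for Surface only, 1 for both caves only and 1 for Surface and Pachon only. Because the statistic changed as well, the fall cannot be put down to width alone. With windows of 250 kb, 6 passed, 3 of them for Tinaja-only regions.

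**Figure D4:**
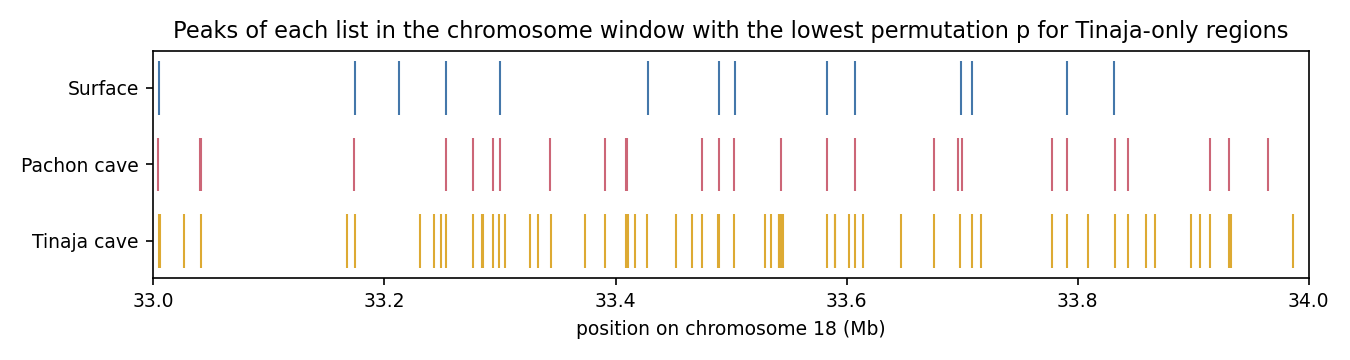
Positions of peaks (vertical lines, at peak midpoints) of the 3 lists along chromosome 18 from 33000001 to 34000000. The window holds 14 Surface, 28 Pachon and 61 Tinaja peaks, and 35 of its 64 regions are Tinaja-only.

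Some runs of neighbouring regions missing from 1 form, or held by it alone, were longer than any in the permutations. On chromosome 19, positions 23255433 to 23515497, 18 consecutive regions over 260 kb had a peak in a cave list and none in Surface, against a highest run of 13 in 200 permutations. On chromosome 23, positions 17497014 to 17740231, 17 consecutive regions over 243 kb lacked a Pachon peak, against a highest permuted run of 15 on chromosomes. On chromosome 13, positions 30178335 to 30262331, 13 consecutive regions over 84.0 kb were Tinaja-only, against a highest permuted run of 8. Each of these 3 had a permutation p of 0.005, the smallest that 200 permutations can give, and 0.00746 after Benjamini-Hochberg adjustment. The runs on chromosomes 23 and 13 lay inside 1 Mb windows already called for Tinaja-only regions (33 of 69 and 35 of 88 regions). They are therefore not separate evidence. On chromosomes, the longest run missing from Tinaja was 10 regions, on chromosome 19, against a highest permuted run of 11 (adjusted permutation p = 0.038), and the longest of Pachon-only regions was 6, on chromosome 14, against a highest of 6 (adjusted permutation p = 0.0199). The longest chromosomal run of Surface-only regions, 6 regions on chromosome 15, did not pass (adjusted permutation p = 0.239).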

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

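The tests of wide peaks and width classes, of counts and windows on chromosomes, of equal numbers of widest peaks, of Surface-only against Pachon-only regions, of both-cave regions against those of Surface and Tinaja, of the sharing excess and of Tinaja's partners were chosen as tests of an explanation only after the result or the data were seen.

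The cave lists departed from Surface in opposite directions: the number of peaks differed by -859 in Pachon and by 11273 in Tinaja, and the covered length by -3816559 bp in Pachon and by 5004817 bp in Tinaja. This difference was not tested, because each form has 1 list. Unplaced scaffolds do not account for the longer Tinaja list, since on chromosomes alone the ratio of Tinaja to Surface peaks was still 1.14 (interval 1.13 to 1.16). Additional narrow peaks close to the caller's threshold stay open: the ratio for peaks of at least 1000 bp was 0.983, but that under 300 bp was 1.13 (upper bound 1.16), close to the 1.13 from 500 to under 1000 bp, with 1.30 between. A difference between Tinaja and Surface livers stays open too.

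Both caves shared more open chromatin with each other than with Surface. For the caves against Surface and Tinaja, the values argue against unequal list length as the whole cause. Tinaja peaks were found more often in Pachon than in Surface by 5.10 points, and those 2 lists are of similar length. That comparison does not bear on the caves against Surface and Pachon, a contrast that the longer Tinaja list favours. There, list length stays open. Settings with equal list lengths do not decide it, since each acts almost only on Tinaja. Equal numbers of widest peaks gave an excess of 4.93 percentage points, but drop Tinaja's narrowest, least shared peaks and so favour its pairs by construction. Equal numbers drawn at random gave -0.391 points and a difference of Jaccard indices of 0.00952, but lower both of Tinaja's pairs by construction. Loss of cave reads on a reference from surface fish would remove regions of both caves and add none, yet these were 1.61 times as numerous as those of Surface and Tinaja, while for the excess of 4.57 points in sharing such loss stays open. The ratio of Surface-only to Pachon-only regions, 1.69, follows from the pattern itself and decides nothing about a Surface list that misses peaks. That, differences between individual fish, and a difference between cave and surface livers may each give this pattern, and 1 list per form separates none of them.

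Windows rich in regions of 1 form, mostly Tinaja-only, were the third pattern. Tinaja-only regions were also the most frequent of the patterns tested against the shared threshold, so whether clustering was particular to Tinaja stays open. On chromosomes alone 18 windows passed the permutation test, 17 for Tinaja-only regions, 1 for both caves and 0 for Surface-only regions, which argues against unplaced scaffolds as the source except for the 2 Surface-only windows, both on scaffolds. Peaks of all 3 forms within the 21 Tinaja-only windows were slightly wider in Tinaja than elsewhere, relative to the mean of the other forms. The difference was 0.0479 on the log2 scale (interval 0.0137 to 0.109). A regional rise of the Tinaja signal, such as extra copies of a segment or wider accessibility, would give this. The windows were picked from the same lists for their many Tinaja-only regions, so the widths are not independent support. Narrower regions in those windows stay open. When patterns were permuted only among regions of similar width, 7 of the 21 passed, but that test also used another statistic. Copy number and sequence differences between the forms were not analysed here.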

How the results depend on the processing

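The alternatives of equal numbers of widest peaks, of windows and widths on chromosomes, of named regions looked up again, the measures of excess in points and of Tinaja's partners, and all those for the ratio to Surface and Pachon regions and for chromosomes led by both caves, were chosen only after the data were seen. No paired analysis was possible because each form has 1 peak list with no values per replicate, and for the same reason no replicate could be left out. The alternatives for gene lists, position relative to genes and motifs were not run, since no genome or annotation of the files' build was used. Of 140 values recomputed under alternatives, 104 stayed within their limits, 34 moved and 2 reversed. Those limits, not given here, were wide: the 104 include a Jaccard difference that fell from 0.0667 to 0.00952 with random thinning. Both reversals came with random thinning to equal length: the excess of cave-cave sharing over the larger cave-surface value, -0.391 percentage points, and the ratio of both-cave to Surface and Pachon regions, 0.983, with both caves leading on 7 chromosomes. That setting removes peaks almost only from Tinaja, so it lowers both of Tinaja's pairs (69.9% for the caves, 63.8% for Surface and Tinaja) and leaves Surface and Pachon at 70.3%, and regions of Surface and Pachon only rise to 10691. Under the other overlaps, the widest 50%, equal numbers of widest peaks, 500 bp peaks and chromosomes alone, the excess ranged from 4.50 to 8.24 points. With random thinning included, Tinaja's partners differed by 4.73 to 8.27 points and, with merging within 200 bp included too, regions of both caves were 1.58 to 1.88 times those of Surface and Tinaja. The difference of Jaccard indices, which does not depend on the overlap rule, was 0.00952 with random thinning and 0.0691 to 0.0741 for the widest 50%, equal numbers of widest peaks, 500 bp peaks and chromosomes alone. Each of these intervals kept its side. Sharing percentages were not computed with merged peaks. With equal numbers of widest peaks, which drop almost only Tinaja's narrowest and least shared peaks, regions of Surface and Pachon only numbered 6598. A reciprocal overlap of 50% gave 22261 Surface-only and 15069 Pachon-only regions, and pair sharing of 66.4% for the caves, 58.1% for Surface and Pachon and 57.1% for Surface and Tinaja. In the same order, sharing was 74.7%, 69.2% and 67.3% for the widest 50% of peaks, 73.6%, 68.3% and 66.65% for 500 bp peaks, and 76.3%, 71.8% and 70.2% on chromosomes. The widest 50%, with fewer peaks by construction, gave 22447 regions of all 3 forms, 6486 of both caves, 2442 of Surface and Pachon, 3834 of Surface and Tinaja, 7681 of Surface only, 4298 of Pachon only and 9061 of Tinaja only. Chromosomes alone held 7768 regions of both caves, 2845 of Surface and Pachon, 5609 of Pachon only and 11867 of Tinaja only. Windows passing fell from 24 to 6 at 250 kb, and the cause was not tested. Depth per peak is unknown here, so a region absent from a list was not called there, which does not show that it was closed.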

Other observations

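The broad regions, the densities and the scaffold runs given here were chosen for description after the data were seen. The broadest regions were largely common to the 3 lists. Their length is that of merged peaks, which favours regions held by more lists. Of 268 regions of at least 5000 bp, 242 (90.3%) were held by all 3 lists, 11 by both caves only, 5 by Surface only, 2 by Tinaja only and 0 by Pachon only. Unplaced scaffolds carried 194 of them (72.4%), against 31.7% of all regions. The longest on a chromosome lay on chromosome 25 at positions 26629846 to 26654902, where peaks covered 23729 bp in Surface, 22010 bp in Pachon and 22605 bp in Tinaja. Chromosome 3 held the next, 16202 bp at positions 53623174 to 53639375 and 15132 bp at positions 6951438 to 6966569, both open in all 3 forms. On chromosome 22, positions 10379408 to 10393810, peaks covered 14403 bp in Surface, 11757 bp in Tinaja and 9829 bp in Pachon.

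Regions were distributed fairly evenly over the chromosomes. Their density, over the span up to the last peak, ran from 59.96 regions per Mb on chromosome 21 to 89.0 on chromosome 8, and chromosome 12 was second lowest with 73.0. Over 944 chromosome windows of 1 Mb the median was 80 regions, with quartiles of 67 and 95. The densest window, on chromosome 14 from 20000001 to 21000000, held 161 regions, of which 59 (36.6%) were open in all 3 forms. In a window of chromosome 25 from 13000001 to 14000000, 81 of 143 regions (56.6%) were open in all 3 forms.

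The longest run of regions missing from Surface was on an unplaced scaffold, with 22 consecutive regions over 455 kb. Another scaffold held 11 consecutive Surface-only regions over 45.3 kb.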
